A study of Oryza sativa with 6 samples.

How the data were processed

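RNA from rice (Oryza sativa) anthers was sequenced in 6 libraries, 3 from wild-type plants and 3 from the dmd1 mutant. The plants were 3 months old, and the series design places the anthers between the tetrad stage and the early microspore stage. Only RNA with an RNA integrity number of at least 6.5 was used, per the labels' protocols. The design text calls the 3 libraries of each genotype biological replicates.

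The authors deposited a single table of FPKM values (fragment counts scaled by transcript length and by the number of mapped fragments), with 1 column per library and 1 row per gene. The submitters' processing notes name fastp, HISAT and RSEM and the genome build IRGSP-1.0, without tool versions. The annotation, the strand setting and any filter are not given in the sources used here. Column names matched the library names in the labels, so no library was assigned by its values. The table has 94013 rows. Of these, 37830 carry rice annotation identifiers that begin with OS, 53250 carry identifiers that begin with EPlOSAG and 2933 begin with MSTRG. The sources used here do not explain the last kind. No pair of libraries held identical values.

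FPKM values are not counts, so no count model was used, the fragment depth of each library is unknown, and no counting interval can be given. The FPKM total per library ran from 808227 to 1287424. Low values held steps that reflect whole fragments, and they gave an approximate relative depth. Set against wild-type library 1, the relative depth was 0.857 in wild-type library 2, 1.08 in wild-type library 3, 0.989 in dmd1 library 1, 1.2 in dmd1 library 2 and 1.46 in dmd1 library 3. The values for dmd1 libraries 1 and 3 are the least certain, because only 8.32% and 5.12% of the low rows lay within 0.02 log2 units of the step.

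Rows were tested when FPKM was at least 1 in at least 3 of the 6 libraries, which left 25474 rows. Values were transformed to log2(FPKM + 1). The contrast dmd1 minus wild type was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust options), without a replicate block, and p-values were adjusted by the Benjamini-Hochberg method. A row was called changed at an adjusted p under 0.05 with a log2 change of at least 1 in either direction. Fold changes are on the log2(FPKM + 1) scale, which understates the change of rows with low values. Errors of log2 changes are standard errors from limma, and errors of FPKM means are SD over 3 libraries. In data simulated for this comparison from the means and spreads of the 25474 rows, the fit recovered 86 of 100 rows changed by 2 log2 units and 91 of 100 changed by 3. Of 15 rows of a simulated list moved by -1, 4 were called, and 11 of the 192 calls were false. The simulated noise was independent between rows, and changed rows were drawn only from rows with higher means. In the real libraries 1 axis held 58.2% of the variance within genotypes, so these rates need not hold for the real data.

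Before the data were examined, 13 gene lists with 150 members were fixed from general knowledge of rice anther biology, each member written as a symbol with its annotation identifier. Of these members, 148 were in the table. The table does not pair identifiers with names, and the reference table used here does not list these identifiers, so the symbols were not checked against an annotation. For the same reason no genome coordinates are given and the level of the DMD1 gene itself was not analysed here. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. The camera test compares a list with all other rows, while fry asks whether the genes of a list move in one direction on balance. The p-values were adjusted over the 13 lists.

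The genes named in the text follow a rule set at the same time. It takes up to 4 tested members with the smallest p from each list on anther and pollen development, up to 2 from each other list, and the rows with the largest rise and fall among called rows without overlap between genotypes and with a mean of at least 5 FPKM. Because most identifiers have no name here, only 2 such rows per direction are given. Other genes are said to be named after their values were seen.

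The libraries share the numbers 1 to 3 between genotypes, but no label ties them, and the numbers were not taken to pair the samples. The alternatives set in advance were another pseudocount, other filters, 3 other scalings, a simpler spread model, library weights, a replicate block and leaving out each library. The library weight was 9.13 for dmd1 library 2, against 0.471 and 0.438 for dmd1 libraries 1 and 3. Calls with library weights thus rest mostly on dmd1 library 2 for the mutant level. After the data were seen, 3 more were added: OS rows only, the main axis of spread within genotypes as a covariate, and leaving out wild-type library 2 and dmd1 library 1 together. The axis came from the same values with genotype means removed, so as a covariate it could not alter any log2 change. With it, all 1709 calls were kept and rows with an adjusted p under 0.05 rose from 3307 to 7438. Passing in that fit therefore adds no support for a gene. Chromosome positions were taken from the identifiers and tested with 100000 random draws of the called status.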

Results

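Anther transcriptomes of wild-type rice and of the dmd1 mutant were compared to find which genes differ in level in anthers between the tetrad and early microspore stages. Each genotype was represented by 3 libraries. Gene symbols are those fixed beside annotation identifiers before the data were examined, not checked against an annotation, and the level of the DMD1 gene itself was not analysed here. Between 24345 and 25389 rows reached 1 FPKM in a library, and the 10 most abundant rows held 10.0% to 15.4% of a library's summed FPKM. The first principal component, with 53.9% of the variance, separated the genotypes. The second set wild-type library 2 and dmd1 library 1 apart from wild-type libraries 1 and 3 and dmd1 library 3, while dmd1 library 2 lay between. No label names a batch for this split. Values within each side of this split rest on 1 or 2 libraries per genotype and allow no test.

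**Figure D1:**
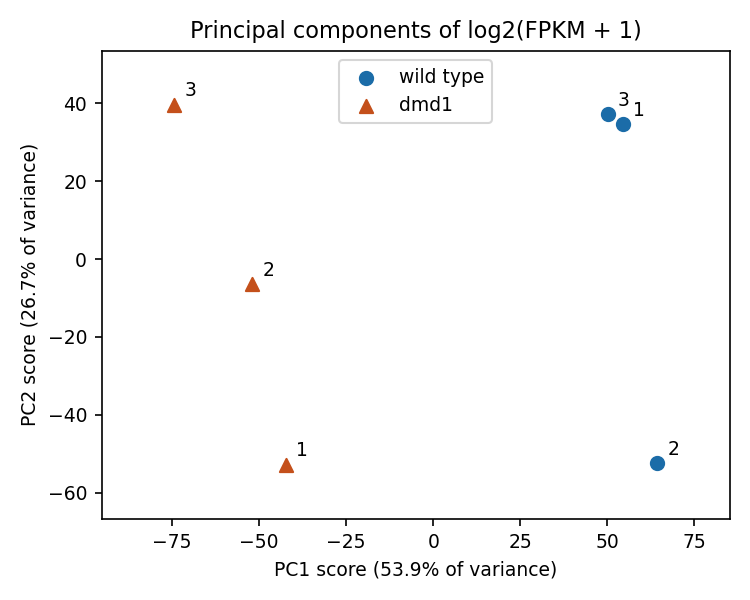
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1) over 25474 rows, with replicate numbers beside the points (circles, wild type; triangles, dmd1). Wild type and dmd1 lie on opposite sides of the first axis, and wild-type library 2 (-52.5) and dmd1 library 1 (-52.8) share the low end of the second.

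Of the 25474 rows tested, 806 were higher and 903 were lower in dmd1 than in wild type (limma, adjusted p under 0.05 and a log2 change of at least 1). The falls were larger than the rises. A log2 change of at least 3 was reached by 143 rows that fell and 31 that rose, and 150 called falls and 91 called rises had a mean over the 6 libraries of at least 100 FPKM. Without a fold minimum, 1988 rows were higher and 1319 lower. All 1709 called rows had no overlap between the genotypes, which the call limits nearly require with 3 libraries per genotype. Of all tested rows 38.4% had no overlap, against 10% by chance for a single row. Rows vary together across the libraries, so these 2 shares give no test over rows. The median change over all tested rows was 0.12. The balance of the calls depended on the scaling, since 63.0% of calls were rises when libraries were scaled to equal totals and 35.4% with median-of-ratios scaling, against 47.2% here. The number of calls fell to 680 without wild-type library 1, 934 without wild-type library 3 and 671 without dmd1 library 2. Fits without 1 library had fewer residual degrees of freedom (3 against 4). A call lost in them need not mean a smaller change.

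Among 13 tested regulators of tapetum and anther wall development, 1 rose, 1 fell and 11 were not called. TIP2 (OS01G0293100), a bHLH factor that acts early in tapetal differentiation, rose from 72.9 ± 9.91 to 252 ± 7.82 FPKM (SD, n = 3), a log2 change of 1.79 ± 0.14 (SE, limma adjusted p = 0.00326). EAT1 (OS04G0599300), a bHLH factor that acts later in the tapetum and promotes its programmed cell death, fell from 502 ± 63.9 to 61.3 ± 43.5 FPKM, a log2 change of -3.30 ± 0.56 (SE, limma adjusted p = 0.0178). PTC1 (OS09G0449000), a PHD-finger regulator of tapetal breakdown, averaged 146 and 58.6 FPKM, with a log2 change of -1.55 ± 0.70 that did not pass (limma adjusted p = 0.19). Over the fits without 1 library its log2 change ran from -2.03 to -0.76. PTC1 passed with the library axis as a covariate (limma adjusted p = 0.037), a fit that leaves the log2 change as it was. TDL1A (OS12G0472500), the ligand of the receptor kinase MSP1, had a log2 change of -0.99 ± 0.39 (limma adjusted p = 0.139). TDR, the bHLH partner of TIP2, stood at 933 FPKM in wild type and 881 in dmd1, and MYB80 at 230 and 218. These values of TDR and MYB80 were chosen after they were seen, and the signs of both turned with equal totals and quantile normalization. The count over the list alone, adjusted over the list alone, was the same 1 rise and 1 fall. The list as a whole did not stand apart (camera adjusted p = 0.335). EAT1 missed the threshold without wild-type library 1 (adjusted p = 0.0724), wild-type library 3 (0.0568) or dmd1 library 2 (0.0651). Its log2 changes in these fits were -3.24, -3.41 and -3.41.

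Genes for sporopollenin, the polymer of the outer pollen wall, and for its export and the anther cuticle were mostly lower in dmd1. Of 19 tested members, 9 fell, 1 rose and 9 were not called, and the median log2 change was -1.40 (camera adjusted p = 0.000102, but adjusted p = 0.527 with an estimated correlation and 0.0727 with fry). When adjusted over the list alone, 11 fell and 1 rose. CYP704B2 (OS03G0168600) and CYP703A3 (OS08G0131100), cytochrome P450 enzymes that hydroxylate fatty acids for sporopollenin, fell from 7960 ± 1282 to 1115 ± 434 FPKM and from 4946 ± 216 to 1130 ± 440 FPKM. Their log2 changes were -2.91 ± 0.36 and -2.22 ± 0.34 (limma adjusted p = 0.00794 and 0.0137). PKS1 (OS10G0484800), a polyketide synthase of the same pathway, fell from 8781 ± 984 to 1962 ± 606 FPKM, a log2 change of -2.21 ± 0.30 (limma adjusted p = 0.0098). The rise was in ABCG3 (OS01G0836600), a transporter gene, from 81.9 ± 9.55 to 195 ± 51.3 FPKM (limma adjusted p = 0.0183). Of these 4, CYP704B2 was called with any library left out. PKS1 was lost without wild-type library 1 (adjusted p = 0.0503). Without wild-type library 1, wild-type library 3 or dmd1 library 2, CYP703A3 (adjusted p = 0.0613, 0.0515 and 0.0507) and ABCG3 (0.0724, 0.0675 and 0.0535) were lost. Photosynthesis genes, markers of green tissue, also had a negative median log2 change (-0.39, with 0.09 and -0.56 on the sides of the library split), but only 1 of 13 was called, and the list passed in camera (adjusted p = 0.00668) and not with an estimated correlation (0.562) or fry (0.213).

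The other 15 tested members of this list were named after their values were seen. The fatty acyl reductase gene DPW, the lipid transfer protein gene C4 and the transporter gene ABCG15 fell, with log2 changes of -3.32, -3.39 and -2.59 (limma adjusted p = 0.0232, 0.0189 and 0.0225). DPW was lost without wild-type library 1 (adjusted p = 0.0842), 2 (0.0522) or 3 (0.0704) or dmd1 library 2 (0.0753), ABCG15 without the same libraries (0.0817, 0.0512, 0.0666 and 0.0671), and C4 without wild-type library 1 (0.0764) or dmd1 library 2 (0.0812) or 3 (0.0522). The tetraketide pyrone reductase genes TKPR1 and TKPR2 and the BURP domain gene RAFTIN1 also fell, with log2 changes of -1.02, -2.09 and -1.52 (limma adjusted p = 0.0436, 0.0406 and 0.023). TKPR1 was lost without wild-type library 1 (adjusted p = 0.105), 2 (0.0794) or 3 (0.123) or dmd1 library 1 (0.0782), 2 (0.0958) or 3 (0.0713), without the filter on low values (0.0636), with the replicate block (0.0868), and with equal totals, quantile normalization and library weights (log2 changes -0.81, -0.61 and -0.76). TKPR2 was lost without wild-type library 1 (0.123), 2 (0.0772) or 3 (0.105) or dmd1 library 2 (0.0957), without the filter on low values (0.0621), with the replicate block (0.0556) and with quantile normalization (0.0734). RAFTIN1 was lost without wild-type library 1 (0.058) or 3 (0.0631) or dmd1 library 2 (0.0841) or 3 (0.0606). C6 (OS11G0582500), another lipid transfer protein gene, was at 9472, 14190 and 10935 FPKM in wild type and at 2039, 360 and 2.39 FPKM in dmd1 libraries 1, 2 and 3. It was not called (limma adjusted p = 0.103), though it passed without dmd1 library 3 (log2 change -3.73, adjusted p = 0.044). C6 also passed with library weights (0.0151), which rest mostly on dmd1 library 2 for the mutant level. Its pass with the library axis as a covariate (0.0388) adds no support. ACOS12, PKS2 and ABCG26 had log2 changes of 0.20, 0.76 and 0.09, and none was called, though PKS2 was called with quantile normalization (log2 change 1.24) and the sign of ABCG26 turned with median-of-ratios scaling. NP1, STRL2, WDA1, CER1 and DEX1 had log2 changes of -1.40, -0.81, -0.77, -0.38 and 0.62 and were not called. NP1 was called with equal totals (adjusted p = 0.0325), median-of-ratios scaling (0.0301) and the library axis as a covariate (0.0261), the last adding no support. WDA1 was called without wild-type library 2 (0.0252) and with library weights (0.00165), which rest mostly on dmd1 library 2 for the mutant level. On the side of the library split with wild-type library 2 and dmd1 library 1 the median of the list was -0.90, and on the other side it was -2.02. The count of 9 falls dropped to 1 without wild-type library 1, 3 without wild-type library 3 and 2 without dmd1 library 2, while the camera result passed each time.

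**Figure D2:**
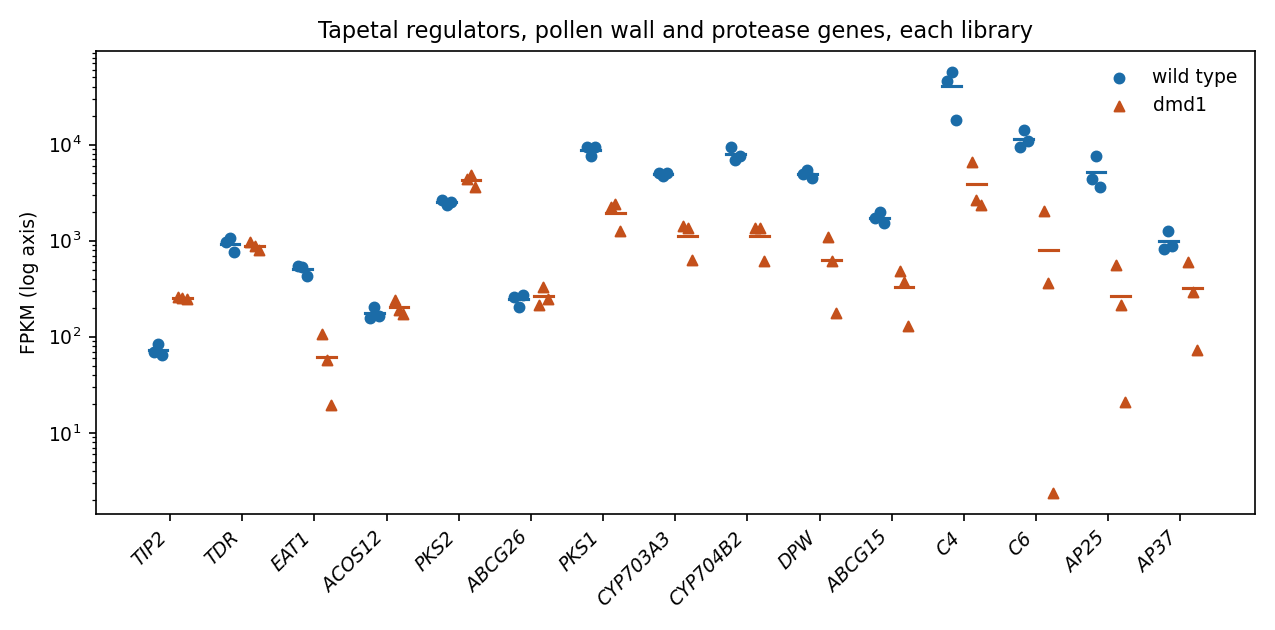
FPKM on a log axis for 15 genes in each library (circles, wild type; triangles, dmd1; bars, group means; n = 3 per genotype). TIP2 was higher in every dmd1 library, TDR, ACOS12 and ABCG26 overlapped between the genotypes, and the dmd1 libraries of C6 and AP25 spread over the widest ranges.

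Proteases and other genes of tapetal breakdown gave 1 fall among 6 tested members. AP25 (OS03G0186900), an aspartic protease gene that EAT1 activates, fell from 5220 ± 2075 to 267 ± 275 FPKM, a log2 change of -5.16 ± 1.13 (limma adjusted p = 0.0343). Its relative AP37 (OS04G0448500) averaged 988 and 322 FPKM and was not called (log2 change -2.05 ± 0.73, limma adjusted p = 0.113). AP37 passed with the library axis as a covariate (adjusted p = 0.0248), which adds no support. It also passed with library weights (0.0156), which rest mostly on dmd1 library 2 for the mutant level. The log2 change of AP37 ran from -2.73 to -1.21 over the fits without 1 library. MTR1 and API5 had log2 changes of -0.72 ± 0.63 and 0.30 ± 0.18 and were not called. The list did not stand apart (camera adjusted p = 0.228), and the count was the same when adjusted over the list alone. The AP25 call was lost without wild-type library 1 (adjusted p = 0.103), 2 (0.0759) or 3 (0.0879) or without dmd1 library 2 (0.0903), and without the filter on low values (0.0558). Over the fits without 1 library the log2 change of AP25 ran from -6.2 to -3.8.

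Of 5 tested genes of late microspores and pollen, 2 fell and none rose. The list had 11 members, 10 of them in the table. The untested MADS62, MADS68, WX, EXPB1 and EXPB13 were at 0.194 FPKM or less in every library of both genotypes. The list thus says little about late pollen genes as a class. The row listed as the MADS-box gene MADS63 (OS06G0217300) fell from 122 ± 26.8 to 53.8 ± 15.8 FPKM (limma adjusted p = 0.037). Neither its symbol nor a role in pollen was checked against an annotation. UGP2 (OS02G0117700), a UDP-glucose pyrophosphorylase gene, fell from 3.22 ± 1.13 to 0.923 ± 0.218 FPKM (limma adjusted p = 0.0341). EXPB10 and AGPS1 had log2 changes of -0.83 ± 0.29 and 0.40 ± 0.16 and were not called. Adjusted over the list alone, the same 2 calls were made, and the list did not stand apart (camera adjusted p = 0.228). With libraries scaled to equal totals neither gene was called, as the log2 changes of MADS63 and UGP2 were -0.99 and -0.98, and without the filter on low values neither was called (adjusted p = 0.0582 and 0.0519). MADS63 was lost without wild-type library 1 (adjusted p = 0.103), 2 (0.0711) or 3 (0.0788) or dmd1 library 2 (0.0997) or 3 (0.0632), and UGP2 without wild-type library 1 (0.101) or 2 (0.0701) or dmd1 library 1 (0.0665), 2 (0.112) or 3 (0.0847). Callose genes showed no call among 3 tested. UGP1 (OS09G0553200), GSL5 (OS06G0182300) and the glucanase gene OS07G0577300 had log2 changes of 0.06 ± 0.19, -0.06 ± 0.29 and 0.06 ± 0.14, and each sign turned under at least 1 other scaling (camera adjusted p = 0.892 for the list, with no member called when adjusted over the list alone).

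Among 7 tested genes of sugar supply, 1 rose. INV4 (OS04G0413200), a cell wall invertase gene, rose from 1.65 ± 0.50 to 4.94 ± 1.07 FPKM (log2 change 1.16 ± 0.22, limma adjusted p = 0.0225). This call was lost without any of wild-type library 1 (adjusted p = 0.0874), wild-type library 3 (0.0789), dmd1 library 1 (0.0656) or dmd1 library 2 (0.0888). The sucrose transporter gene SUT1, the invertase gene CIN2 and the monosaccharide transporter gene MST7 had log2 changes of 0.90 ± 0.27, -0.64 ± 0.20 and -0.87 ± 0.44, none called, though SUT1 was called with equal totals (log2 change 1.08) and without wild-type library 2 (1.12). The list did not stand apart (camera adjusted p = 0.959), and adjusted over the list alone 1 member rose.

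No meiotic gene passed both limits among 14 tested, but 3 passed the adjusted p alone, all higher in dmd1. The cohesin gene REC8 (OS05G0580500) averaged 3.64 ± 0.13 and 7.47 ± 0.76 FPKM, HEI10 (OS02G0232100) 3.76 ± 0.21 and 7.07 ± 0.62 FPKM, and the recombinase gene RAD51C (OS01G0578000) 7.99 ± 1.01 and 12.2 ± 0.49 FPKM (limma adjusted p = 0.0147, 0.0202 and 0.0404). ZIP4 had a log2 change of 1.12 ± 0.37 and did not pass (limma adjusted p = 0.0947). Adjusted over the list alone the same number passed, and the list did not stand apart (camera adjusted p = 0.228). Of 8 mitotic cell cycle genes, 4 passed the adjusted p alone, all higher in dmd1, and none reached the fold minimum. They included the replication clamp gene PCNA (OS02G0805200), at 20.7 ± 1.62 and 39.3 ± 2.28 FPKM, and CDKA2 (OS02G0123100), at 7.42 ± 0.44 and 13.1 ± 1.71 FPKM (limma adjusted p = 0.00866 and 0.0214). For this list fry gave an adjusted p = 0.0476 and camera an adjusted p = 0.105, or 0.527 with an estimated correlation. Scaled to equal totals, REC8, ZIP4 and PCNA passed both limits (log2 changes 1.04, 1.31 and 1.09). REC8 also did so with a pseudocount of 0.1 (1.02, adjusted p = 0.0153), and ZIP4 with library weights (1.35), without wild-type library 2 (1.55) and with the library axis as a covariate (1.12, adjusted p = 0.0147). For ZIP4 the weighted fit rests mostly on dmd1 library 2 for the mutant level, and passing with the axis adds no support. RAD51C was lost with median-of-ratios scaling (adjusted p = 0.0587) and without the filter on low values (0.0585), CDKA2 was lost with quantile normalization (0.0539) and median-of-ratios scaling (0.0595), and camera passed the cell cycle list without the filter on low values (adjusted p = 0.0358). Without wild-type library 1, wild-type library 3 or dmd1 library 2, the adjusted p was 0.0653, 0.0546 and 0.0735 for REC8, 0.0717, 0.0761 and 0.0889 for HEI10, 0.13, 0.126 and 0.132 for RAD51C and 0.08, 0.067 and 0.0812 for CDKA2, while PCNA stayed under 0.05 with each library left out. RAD51C was also lost without dmd1 library 1 (0.111), and without dmd1 library 3 HEI10 (0.0564), RAD51C (0.0817) and CDKA2 (0.0533) were lost.

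The redox list moved in both directions, with 2 rises and 1 fall among 9 tested genes. MNSOD (OS05G0323900), the manganese superoxide dismutase gene, rose from 210 ± 13.5 to 439 ± 37.9 FPKM, and APX2 (OS07G0694700), an ascorbate peroxidase gene, fell from 357 ± 62.7 to 167 ± 40.8 FPKM (limma adjusted p = 0.00904 and 0.0306). The other rise, named after its value was seen, was in the catalase gene CATA, from 4.87 to 31.8 FPKM (log2 change 2.26, limma adjusted p = 0.04). It was lost without the filter on low values (adjusted p = 0.0637), with the replicate block (0.0761) and without wild-type library 1 (0.119), 2 (0.0852) or 3 (0.095) or dmd1 library 1 (0.0948) or 2 (0.126). MNSOD fell under the fold minimum with median-of-ratios scaling (log2 change 0.93), and APX2 did so with equal totals (-0.91). Of 5 tested defence genes, 2 fell and 1 rose. WRKY76 (OS09G0417600), a WRKY factor gene, was at 17.9, 48.5 and 19.4 FPKM in wild type and at 0.193, 0 and 0.034 FPKM in dmd1 (limma adjusted p = 0.0035). WRKY45 (OS05G0322900) fell from 15.9 ± 1.48 to 4.37 ± 2.24 FPKM (limma adjusted p = 0.0174), and the chitinase gene CHT1, named after its value was seen, rose (log2 change 2.26, limma adjusted p = 0.045). The CHT1 call was lost with a pseudocount of 0.1 (adjusted p = 0.0505), without the filter on low values (0.0705), with the replicate block (0.109) and without wild-type library 1 (0.135) or 2 (0.0902) or dmd1 library 1 (0.123) or 2 (0.137). Adjusted over the list alone, the redox list held the same calls and the defence list 2 rises and 2 falls. Neither list stood apart (camera adjusted p = 0.835 and 0.758). WRKY76 was called with any library left out, while WRKY45 was lost without wild-type library 1 (adjusted p = 0.0687), wild-type library 3 (0.0587) or dmd1 library 2 (0.0722). MNSOD was lost without dmd1 library 2 (adjusted p = 0.0527) or 3 (log2 change 0.99), and APX2 without wild-type library 1 (adjusted p = 0.102) or 3 (0.0788) or dmd1 library 2 (0.0933) or 3 (0.0579).

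Lists that stand for stress, handling or other tissue were tested in the same way. Of 10 heat shock genes, 1 rose, a small heat shock protein gene (OS03G0266900, from 2.10 ± 0.65 to 12.3 ± 5.39 FPKM, limma adjusted p = 0.0202), while HSP90 (OS08G0500700) had a log2 change of -0.61 ± 0.20 and was not called. None of 8 genes of protein folding in the endoplasmic reticulum was called. In that list the chaperone genes BIP1 and CRT had log2 changes of -0.35 ± 0.26 and 0.25 ± 0.21. Neither list stood apart (camera adjusted p = 0.758 for both). Photosynthesis genes, markers of green floral tissue that the anther wall also expresses, had a median log2 change of -0.39 (camera adjusted p = 0.00668 at the preset correlation, but adjusted p = 0.562 with the estimated correlation of 0.545 and 0.213 with fry). The light-harvesting gene CAB2R (OS01G0600900) was the 1 called fall of 13 tested members, from 157 ± 53.9 to 48.1 ± 14.1 FPKM, and PSAD (OS08G0560900) averaged 112 ± 10.4 and 78.5 ± 1.11 FPKM (limma adjusted p = 0.0223 and 0.0445). The median was 0.09 on the side with wild-type library 2 and dmd1 library 1 and -0.56 on the other side. The camera call was lost without wild-type library 3 (adjusted p = 0.12) and with quantile normalization (0.0656). Without wild-type library 1, wild-type library 3, dmd1 library 1 or dmd1 library 2, neither the small heat shock gene (adjusted p = 0.0789, 0.0688, 0.0533 and 0.0798), CAB2R (0.0713, 0.0739, 0.0657 and 0.0865) nor PSAD (0.137, 0.14, 0.117 and 0.148) passed, and PSAD also missed without dmd1 library 3 (0.1), with equal totals (0.338), with quantile normalization (0.193), without the filter on low values (0.0608) and with the simpler spread model (0.0504).

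Within the sides of the library split, the side with wild-type library 2 and dmd1 library 1 first, list medians differed in sign for callose (-0.32 and 0.20), sugar supply (0.46 and -0.14) and photosynthesis. Medians were -0.15 and -0.09 for tapetal regulators, -0.79 and -0.29 for tapetal breakdown, -0.98 and -1.20 for late microspores and pollen, 0.32 and 0.30 for meiosis and 0.46 and 0.78 for the cell cycle. They were 0.14 and 0.21 for redox genes, 1.06 and 0.19 for defence, -0.06 and -0.12 for heat shock and -0.24 and -0.02 for protein folding. Among the genes named by the rule, signs differed between the sides for MTR1 (-1.67 and 0.91), UGP1 (-0.32 and 0.48), the glucanase gene OS07G0577300 (-0.03 and 0.20) and CRT (-0.01 and 0.30), and none of these was called.

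**Figure D3:**
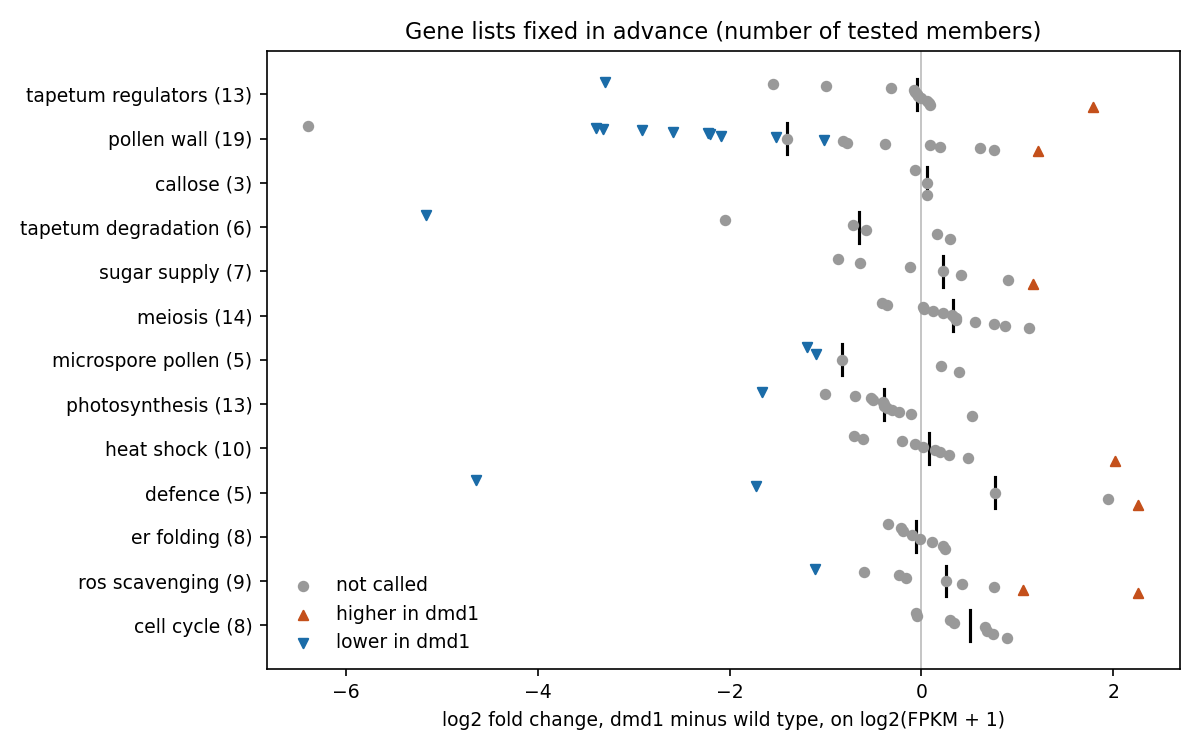
Log2 change (dmd1 minus wild type, on log2(FPKM + 1)) of each tested member of the 13 lists, with the number tested in parentheses (upward triangles, called higher in dmd1; downward triangles, called lower; grey circles, not called; vertical bars, list medians). The pollen wall list has 9 called falls and a median of -1.40, the lowest of the 13.

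Among called rows with a mean of at least 5 FPKM, the largest rise was in OS03G0115800, listed at 0, 0 and 0.05 FPKM in wild type and at 217, 232 and 216 FPKM in dmd1 (limma adjusted p = 2e-06). MSTRG.31735 followed, at 0.063 FPKM or less in wild type and at 65.1, 66.6 and 50.8 FPKM in dmd1. Both rows, and WRKY76, belong to 23 rows with at least 5 FPKM in all 3 libraries of 1 genotype and under 0.5 FPKM in all 3 of the other, and the source of this on and off pattern stays open. The largest falls were in OS06G0237400, from 757 ± 397 to 24.6 ± 27.8 FPKM, and OS09G0401000, from 549 ± 158 to 27.6 ± 32.3 FPKM (limma adjusted p = 0.0344 and 0.0337). Without wild-type library 1, 2 or 3 or dmd1 library 2, both falls were lost, with adjusted p = 0.0999, 0.0766, 0.0909 and 0.0891 for OS06G0237400 and 0.101, 0.0744, 0.0922 and 0.0937 for OS09G0401000. Without the filter on low values they were also lost (0.0563 and 0.055), and OS06G0237400 was lost with a pseudocount of 0.1 (0.0563). The sources used here give no names for these rows.

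Called genes were spread over all 12 chromosomes. Chromosome 2 held 129 called genes against 169.8 for an even spread (two-sided permutation p = 0.00071, adjusted p = 0.00852 over 12 chromosomes), and no other chromosome passed. This result was lost without the filter on low values, with equal totals or median-of-ratios scaling and on leaving out any of the 6 libraries.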

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

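The library axis covariate, the joint removal of wild-type library 2 and dmd1 library 1, and the restriction to OS rows were chosen after the data had been seen. As FPKM values carry no counts, depth could not be used to weight rows or libraries. The number of changed rows was 1709, and it rose to 2672 with library weights and to 3307 without a fold minimum. Leaving out 1 library at a time gave 671 to 1605 changed rows, 332 to 923 rises and 323 to 891 falls. Rises numbered 1494 with equal totals and 1470 with library weights. The other alternatives run for these 3 counts stayed within 1.5 times. The replicate block gave 1395 changed rows, of which 1311 were shared with the fit without it. Same-numbered libraries deviated from their group means with correlations of -0.346, -0.0123 and 0.346, and not every library correlated best with its own number, so no pairing was assumed. With the block, HEI10, RAD51C, CDKA2, PSAD, CATA, CHT1, TKPR1 and TKPR2 no longer had an adjusted p under 0.05 (0.0653, 0.0934, 0.054, 0.106, 0.0761, 0.109, 0.0868 and 0.0556), and the pollen wall list held 7 falls. With both libraries removed, UGP2, MADS63, PSAD, RAD51C, CATA, CHT1, TKPR1, TKPR2 and the small heat shock gene missed (0.0924, 0.0531, 0.0501, 0.0528, 0.138, 0.165, 0.0934, 0.0639 and 0.0562), and ZIP4 was called (log2 change 1.42). With library weights, TDL1A, AP37 and MTR1 were called (adjusted p = 0.0103, 0.0156 and 0.0442) and MADS63 was not (log2 change -0.94). Of the 13 lists, 2 passed in camera (pollen wall and photosynthesis). Without the low-value filter 3 passed (the cell cycle as well), with quantile normalization 1 (pollen wall), with fry 1 (the cell cycle, neither of the 2) and with an estimated correlation 0, and leaving out 1 library gave 1 to 2. The single chromosome that passed became 0 without the low-value filter, with equal totals, with median-of-ratios scaling, with the replicate block, with both libraries removed and in each fit that left out 1 library (0 to 0), 2 with quantile normalization and 3 with the library axis covariate. Equal totals moved the median of all rows from 0.12 to 0.29. Signs turned where log2 changes or list medians lay near 0, and also in the defence list. The defence median was 0.77 over 5 tested members in the main fit, and 14 members were tested without the filter on low values. The median of tapetal regulators became 0.15 with equal totals and 0.0122 with quantile normalization, that of callose genes -0.0351 with quantile normalization and -0.0674 with median-of-ratios scaling, that of heat shock genes -0.00745, -0.0422 and -0.0226 with quantile normalization, median-of-ratios scaling and library weights and -0.0402 with both libraries removed, that of defence genes -0.0114 without the filter and -1.73 with the stricter filter (3 members tested), and that of folding genes 0.15, 0.061, 0.13 and 0.11 with equal totals, quantile normalization, library weights and both libraries removed. The glucanase gene OS07G0577300 turned to -0.0351 and -0.0597 with quantile normalization and median-of-ratios scaling, UGP1 to -0.0674 with the latter, and GSL5 to 0.0752, 0.21 and 0.10 with equal totals, library weights and both libraries removed. TDR turned to 0.13, 0.38 and 0.00286 and MYB80 to 0.13, 0.0122 and 0.12 with equal totals, quantile normalization and library weights, and ABCG26 to -0.0416 with median-of-ratios scaling. Leaving out 1 library gave medians from -0.11 to 0.000898 for tapetal regulators, -0.0446 to 0.15 for callose, -0.0337 to 0.37 for sugar supply, -0.0601 to 0.16 for heat shock and -0.20 to 0.16 for folding genes, and log2 changes from -0.0355 to 0.15 for the glucanase gene, -0.098 to 0.17 for UGP1, -0.34 to 0.16 for GSL5, -0.21 to 0.0351 for TDR, -0.19 to 0.00738 for MYB80 and -0.0822 to 0.23 for ABCG26. The causes of these moves were not tested.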

Other observations

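The pollen wall list held 8.91% ± 1.09 of summed FPKM in wild type and 2.04% ± 0.52 in dmd1 (SD, n = 3, two-sided exact permutation p = 0.1, the smallest this design allows). The lipid transfer protein gene C4 alone held 4.53%, 4.44% and 1.96% of the wild-type libraries and 0.632%, 0.289% and 0.287% of the dmd1 libraries. Genes of tapetal breakdown held 0.592% ± 0.108 and 0.0888% ± 0.0459, and redox genes 0.175% ± 0.023 and 0.238% ± 0.034 (exact permutation p = 0.1 each). The drop for tapetal breakdown came mostly from AP25, at 5220 FPKM in wild type and 267 in dmd1. AP37 (988 and 322), MTR1 (49.8 and 33.6) and RBOHE (4.11 and 1.95) were also lower on average. CP1 (141 and 152) and API5 (66.5 and 81.0) were not. Of the 50 rows highest in wild type, 21 were called lower and 3 higher in dmd1, and of the 50 highest in dmd1, 19 were called higher and 5 lower, with 23 rows in both sets. Over all tested rows, 1709 of 25474 were called. Choosing rows by their level in 1 genotype itself favours falls in the first set and rises in the second.

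All tests of explanations in this section were chosen after the results they bear on had been seen, except the count of rows in dmd1 library 1 under 0.25 of the share of the wild-type level that C6 kept there (the C6 share). That count decided nothing, and the 2 counts of rows under 1% were chosen after it. The ratio for the library axis was first taken over all called falls, and the ratio over 128 rows was chosen after it. The real split of the libraries gave 1709 changed rows, and the highest of the other 9 splits gave 10. That is 1 of 10 splits, too few for a share under 0.05.

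Among called falls, wild-type library 2 exceeded wild-type libraries 1 and 3 by a median of 0.40 log2 units and dmd1 library 1 exceeded dmd1 library 3 by 0.64, against 0.13 and 0.19 over all tested rows. Among 128 rows with at least 5 FPKM in every wild-type library and under 2% of the wild-type mean in dmd1 library 3, the median share of the wild-type level was 15.5% in dmd1 library 1 (quartiles 10.8% and 21.5%) and 5.22% in dmd1 library 2 (quartiles 3.29% and 7.38%), 32 of these rows were not called, and of 3 list members among them C6 and AP25 kept a share (AP25 at 10.8% and 4.12%), while WRKY76 was at 0.675% and 0%. RNA of the wild-type plants mixed into dmd1 library 1 is argued against as the whole cause, since of 9 rows with at least 5 FPKM in every wild-type library and under 1% of the wild-type mean in dmd1 libraries 2 and 3, all of which it would lift, 6 were also under 1% in dmd1 library 1, as were 10 of all 14513 rows with at least 5 FPKM in every wild-type library, although 2 of 6327 rows with at least 20 FPKM there lay under 0.25 of the C6 share, too few to decide. The library axis cannot be told apart, since the wild-type gap was 0.623 of the dmd1 gap over the 903 called falls, which goes with it, and 0.244 over the 128 rows (medians of 0.80 and 3.27 log2 units), which were picked for low values in dmd1 library 3. A candidate explanation that also stays open is that further developed anthers, or normal siblings from the mutant line, were pooled into dmd1 libraries 1 and 2: the upper quartile of the share was 1.99 and 2.24 times the lower in these libraries, which does not decide it, and no label gives the stage of each pool.

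A second pattern crosses the genotypes. In all, 24 rows were at 5 FPKM or more in both wild-type library 2 and dmd1 library 1 and under 0.5 FPKM in wild-type libraries 1 and 3 and dmd1 library 3, or the reverse. Sequencing depth is argued against, since 9 of them had at least 20 FPKM on 1 side and exactly 0 on the other. Of the 23 such rows with OS identifiers, 17 (73.9%) had numbers that do not end in 00, against 9.54% of the other tested OS rows (two-sided Fisher's exact p = 2.73e-13). The rows are not all independent, as OS02G0644466 and OS02G0645266 held identical values in every library. The share of identifiers not ending in 00 was chosen as an indirect sign of reads assigned differently between neighbouring gene models. No neighbouring row was examined, so this explanation stays open. The rule for these rows leaves out dmd1 library 2. Whether the libraries were made or sequenced apart stays open, as the labels give no batch, and no biological explanation was tested.

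Another pattern follows the genotypes. A further 23 rows were at 5 FPKM or more in all 3 libraries of 1 genotype and under 0.5 FPKM in all 3 of the other, 10 of them on in wild type (WRKY76 among them) and 13 on in dmd1 (OS03G0115800 and MSTRG.31735 among them). Of the 12 with OS identifiers, 2 pairs lay within 20 tested rows of each other on a chromosome, on chromosomes 10 and 11, against a mean of 0.117 pairs in 100000 random draws (one-sided permutation p = 0.0059). Segments of differing parental sequence between the wild-type and mutant plants remain a hypothesis that rests on 4 rows. Called genes as a whole did not gather on these chromosomes. Chromosome 10 held 57 against 71.1 for an even spread (permutation adjusted p = 0.234), and chromosome 11 held 81 against 78.8 (0.811). The draws placed rows independently, so they make no allowance for neighbouring genes that vary together. Read assignment cannot be told apart from such segments. Identifiers not ending in 00, the same indirect sign as above, made up 16.7% of the 12 rows against 9.6% of the others (two-sided Fisher's exact p = 0.323). An effect of the mutation itself was not tested.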
